A study of Homo sapiens with 8 samples.

How the data were processed

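Total RNA from MIA PaCa-2 cells, a human pancreatic cancer line, was measured on 8 one-colour Agilent expression microarrays. Per the labels, 4 biological replicates stably expressed a short hairpin RNA against TRIP12 (shTRIP12) and 4 expressed a control hairpin (shControl). The labels' protocols describe Trizol extraction from exponentially growing cells and Cy3 labelling with a one-color kit. The hairpin sequences were not given in the sources used here. The series is typed as sequencing in its record, but each deposited sample file is the output of Agilent Feature Extraction 10.10.1.1 for 1 array.

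The deposited values are spot intensity values: per the file headers, the processed Cy3 intensity is background-subtracted and detrended within each array and not scaled between arrays, with low values replaced by surrogates. The other deposited columns used are 0 or 1 flags set per spot by the image software, for signal well above background, saturation and non-uniform or outlying pixels. The submitters' processing notes name limma without a step or version. Per the file headers the array design was placed on genome build hg19, and every coordinate in the text is from that build as the files give it. The reference annotation on build GRCh38 (GENCODE release 29 and the RefSeq genes) served for gene names, transcript sequences, untranslated regions and host genes, and never for coordinates.

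Each array held 62976 spots, of which 58717 were not controls and measured 50599 probes. Spots with a non-uniformity or population flag were left out, and 25 probes without an unflagged spot on some array were dropped. The log2 processed intensity minus the array's 75th percentile over non-control spots was averaged over the spots of a probe. Probes were renamed to current symbols through 28174 RefSeq accessions, 3556 Ensembl transcripts, 1510 current symbols and 434 older symbols, and 16925 probes kept the name in the files. A probe was kept if it was well above background on all 4 arrays of at least 1 group, which left 27142 probes. The probe with the highest mean over the 8 arrays stood for each gene name, which gave 20372 genes, 14741 of them with a gene symbol. An array has no read depth. Its counterpart here is the share of probes well above background, which was 53.4% to 60.7% per array, and the number of arrays limits the precision.

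The comparison was shTRIP12 against shControl over all 8 arrays, without covariates, with the moderated test of limma 3.58.1 (lmFit and eBayes) in R 4.3.3. P-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Values are given as the log2 fold change with the standard error (SE) of the fit, or as mean ± SD with n = 4. Single values such as the TRIP12 level also have a two-sided exact permutation test over the 4 against 4 arrays, whose smallest possible p is 0.0286. A gene above background on every array of 1 group and on none of the other has a lower bound on its fold. The bound compares the detected group's mean with the mean of the other group after each of its values was raised to the lowest signal called well above background on that array, and is written as "at least". It applies to the main scaling only.

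Before the data were examined, the test, the main scaling, the alternatives listed as planned, 37 gene lists (pathways, complexes, cell types) and the rule for named genes were fixed. The rule names TRIP12; the 12 largest rises and 12 largest falls among symbol-named genes with adjusted p under 0.05, no overlap between groups, and signal above background and unsaturated on all 8 arrays; the 3 highest lower bounds in each direction; up to 4 passing members of each list that passes; and up to 2 passing members of any other list. It passes over a withheld symbol and takes the next gene, and some results are not reported here. It named 99 genes. Lists were tested against the other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists, with camera at an estimated correlation and fry beside it. Chromosomes 1 to 22 and X were tested with camera in the same way, adjusted over 23 chromosomes. Probe sequences of the named genes were searched in all annotated transcripts: 89 matched 1 gene, 4 matched several and 6 had no exact match.

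The alternatives were normexp background with quantile normalization, quantile normalization alone, scaling to the array median or to the 75th percentile of probes above background on all arrays, no filter on dim probes, a filter on all 8 arrays, the mean of a gene's probes, every probe on its own, a variance trend with robust hyperparameters, array weights, slide as a block, each slide alone, replicate number as a block, and leaving out each array in turn. Added after the data were seen were leaving out shTRIP12 replicate 3 and shControl replicate 2 together, a loess correction for probe GC content, and leaving out the genes of chromosome 11. The normexp setting added an offset of 50 to the corrected intensities. The counts were also recomputed for all 35 splits of the 8 arrays into 4 and 4.

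The steps were tested on simulated data with known changes added to the measured spread, in 10 runs with 200 changed genes each. A change of 1.41-fold was recovered for 8% of genes, of 2-fold for 61.8%, of 4-fold for 90.8% and of 16-fold for 99.2%. Of the calls, 5.60% were false. Most changes of about 1.41-fold were thus missed in the simulation, so a gene that did not pass may still differ. The simulated genes varied independently and with 1 spread for both groups, unlike the measured ones. Each run also held 200 changed genes, whereas 2986 genes passed in the data. With fewer changed genes the Benjamini-Hochberg adjustment is stricter, so these shares may understate the recovery in the data. Data handling used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (version 1.17.8). Control spots were left out except the E1A spike-in RNAs, which are reported as a check of labelling. The Y chromosome was left out.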

Results

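Gene expression was measured in MIA PaCa-2, a human pancreatic cancer cell line, stably expressing a short hairpin RNA against TRIP12 (shTRIP12, n = 4) or a control hairpin (shControl, n = 4). TRIP12 encodes a ubiquitin ligase of the HECT family. The comparison of the groups asks which transcripts differ when TRIP12 is depleted. Each replicate was hybridised to 1 one-colour array with 50599 probes. Between 27031 and 30706 probes per array (53.4% to 60.7%) were well above background, the 75th percentile of signal lay between 391.98 and 555, and 0 probes were saturated. Across probes, which are not independent replicates, Pearson's r was 0.988 to 0.997 between shControl arrays, 0.979 to 0.990 between shTRIP12 arrays and 0.965 to 0.985 between the groups. The median SD of a gene was 0.16 log2 units in shControl and 0.26 in shTRIP12. The arrays lay on 2 slides, each with 2 arrays of each group. All shControl arrays lay in slide column 3 and all shTRIP12 arrays in column 4, so the column and the group cannot be separated. Labelling spike-in RNAs lay at 0.90 ± 0.24 log2 units relative to the 75th percentile in shControl and 1.11 ± 0.24 in shTRIP12 (SD, n = 4, two-sided exact permutation p = 0.229).

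TRIP12 itself was lower in every shTRIP12 array. Its transcript level was 13.8% ± 5.01 of the shControl geometric mean in shTRIP12 and 101% ± 13.5 in shControl (SD, n = 4). The shTRIP12 replicates 1 to 4 retained 17.4%, 18.01%, 7.24% and 12.6%. The probe lies on the minus strand of chromosome 2 at 230631938 to 230631997 (hg19), in the 3′ untranslated region (3′ UTR). The log2 fold change was −2.94 (SE 0.28), 7.68-fold lower, with a limma adjusted p of 0.000569 and the smallest two-sided exact permutation p that 4 against 4 arrays allow, 0.0286. It was −3.25 on slide 1 alone and −2.63 on slide 2 alone, and the limma adjusted p with slide as a block was 0.00174. The other TRIP12 probe, at 230695793 to 230695852, is dimmer and matches the 3′ UTR of a different transcript. It did not fall, with a log2 fold change of 0.38 (SE 0.20, limma adjusted p = 0.241, exact permutation p = 0.171), so the 2 probes give opposite signs. With the mean of both probes the log2 fold change was −1.28.

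**Figure D1:**
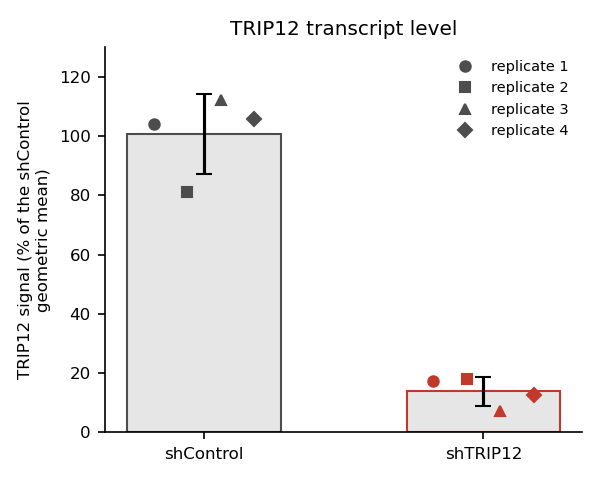
TRIP12 transcript level of each array as a percentage of the shControl geometric mean (points), with bars for the group mean and error bars for the SD (n = 4). The shTRIP12 arrays lie between 7.24% and 18.01%, and the shControl arrays between 81.2% and 112%.

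Depletion went with changes in many other transcripts. On the main scale, genes for an ion channel subunit and a tight-junction protein rose more than 10-fold. Genes for a tetraspanin, a transmembrane collagen and a glutathione-processing enzyme fell more than 10-fold there. Of 20372 genes tested, 2986 (14.7%) had a limma adjusted p under 0.05, 1574 higher and 1412 lower in shTRIP12. A change of at least 2-fold was present in 1022 of them, 620 higher and 402 lower. At an unadjusted p under 0.05 there were 6088 genes, and 4525 genes (22.2%, against 2.86% by chance) had no overlap between the groups. The even split between directions depends on the scale: with each array set to its median in place of its 75th percentile, the median of all genes moved from 0.03 to −0.14 and the changed genes were 894 higher and 2654 lower. Scaled to the 75th percentile of probes above background on all arrays, the median was 0.09 and the changed genes were 1994 higher and 1206 lower. With slide as a block 3074 genes passed, and within slide 1 and slide 2 alone, with 2 arrays per group, 445 and 142. Leaving out shControl replicate 1, 3 or 4 lowered the count to 1389, 1770 or 1323.

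Among symbol-named genes above background on all 8 arrays without overlap between the groups, the largest rise was in KCNMB4, a regulatory subunit of calcium-activated potassium channels, at 13.6-fold (log2 3.76, SE 0.36, adjusted p = 0.00059, limma). Its rank is that of the main scale. Over the alternatives its log2 fold change ran from 2.23 to 4.13, and that of CLDN4 from 3.24 to 3.74. GDF15, a secreted cytokine induced by cell stress, rose 11.9-fold (log2 3.58, SE 0.70, limma adjusted p = 0.0113). CLDN4, a claudin of tight junctions, rose 10.96-fold (log2 3.45, SE 0.22, limma adjusted p = 8.6e-05). PDE4DIP, which encodes the centrosome and Golgi protein myomegalin, rose 11.7-fold, but its 15 probes ranged from −0.03 to 3.55 log2 and the probe used also matches AC241952.1. Keratin genes of hair, KRT86 and KRT83, rose 11.6-fold and 10.3-fold. The KRT86 probe has no exact match in the annotated transcripts, and its call ended without shControl replicate 4 (limma adjusted p = 0.0525). The KRT83 call ended without shControl replicate 1, 3 or 4 (limma adjusted p = 0.0649, 0.0592 and 0.0663). Without shTRIP12 replicate 3 the log2 fold changes were smaller, 2.83 for GDF15, 2.72 for KRT86 and 2.59 for KRT83, and without shTRIP12 replicate 1 they were 4.13 for KRT86 and 4.05 for KRT83. ADAM19, a membrane metalloprotease, rose 9.36-fold, and STRA6, the receptor for retinol-binding protein, 8.69-fold. RAB39B, a vesicle GTPase, rose 8.42-fold and MSRB3, a methionine sulfoxide reductase, 8.13-fold. Over the alternatives the log2 fold change ran from 1.71 to 3.40 for ADAM19, 1.94 to 3.40 for RAB39B and 1.43 to 3.19 for MSRB3. The mitochondrial enzymes GLDC, of glycine cleavage, and CKMT1A, a creatine kinase, rose 8.10-fold and 7.91-fold. In all 12 of these genes the 4 shTRIP12 arrays lay above the 4 shControl arrays.

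Under the same limits the largest fall was in TSPAN1, a tetraspanin of the cell surface, on chromosome 1, at 28.1-fold (log2 −4.81, SE 0.59, limma adjusted p = 0.00165). COL13A1, a transmembrane collagen, fell 22.7-fold (log2 −4.50, SE 0.91, limma adjusted p = 0.0134), with an SD of 2.26 in shTRIP12. Without shTRIP12 replicate 2 the log2 fold change was −5.42 for TSPAN1 and −5.57 for COL13A1. GGT5, a gamma-glutamyltransferase, fell 11.1-fold and PNMA2, a paraneoplastic antigen gene, 9.35-fold. GABBR2, a subunit of the GABA-B receptor, fell 8.55-fold. DDAH1, which degrades asymmetric dimethylarginine, fell 7.95-fold (log2 −2.99, SE 0.13, limma adjusted p = 7.2e-06), while its other probe stood at 0.15. The receptor tyrosine kinase-like gene ROR1 fell 7.79-fold on the probe used, with its 3 probes between −3.10 and −0.36. DPYSL2, a regulator of microtubule assembly, fell 7.14-fold, the peptide ligand gene APLN 6.91-fold and the nucleotide receptor gene P2RY2, on chromosome 11, 5.91-fold. These folds are those of the main scale. Over the alternatives the log2 fold change ran from −3.30 to −1.53 for APLN and from −4.94 to −2.01 for GGT5. The small nucleolar RNAs SNORA48 and SNORA44, which guide RNA pseudouridylation, fell 9.03-fold and 6.35-fold. Their probes also match the host transcripts EIF4A1 and SNHG12.

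Other genes were at background in 1 group. IFI44, an interferon-induced gene, was at least 24.7-fold lower in shTRIP12, where no array was above background, though its shControl values had an SD of 2.43 log2 units. Its fitted log2 fold change, which is no bound, was −7.24 without shControl replicate 2 and −5.28 without shControl replicate 3. TRIM59, a tripartite motif gene, was at least 16.1-fold lower and PLSCR1, an interferon-inducible phospholipid scramblase, at least 10.4-fold lower. These bounds hold on the main scale only. Over the alternatives the fitted log2 fold change was as small as −2.29 for IFI44, −1.65 for TRIM59 and −1.40 for PLSCR1. In the other direction SGCE, a sarcoglycan gene, was at least 11.98-fold higher, NRP1, a co-receptor for semaphorins, at least 9.87-fold higher, and IL18, an inflammatory cytokine gene on chromosome 11, at least 9.71-fold higher. In total 22 genes were above background on all shControl arrays and no shTRIP12 array, and 91 the reverse. Over the whole array 27963 ± 796 probes were above background in shControl and 29378.5 ± 982 in shTRIP12 (SD, n = 4, two-sided exact permutation p = 0.0571).

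**Figure D2:**
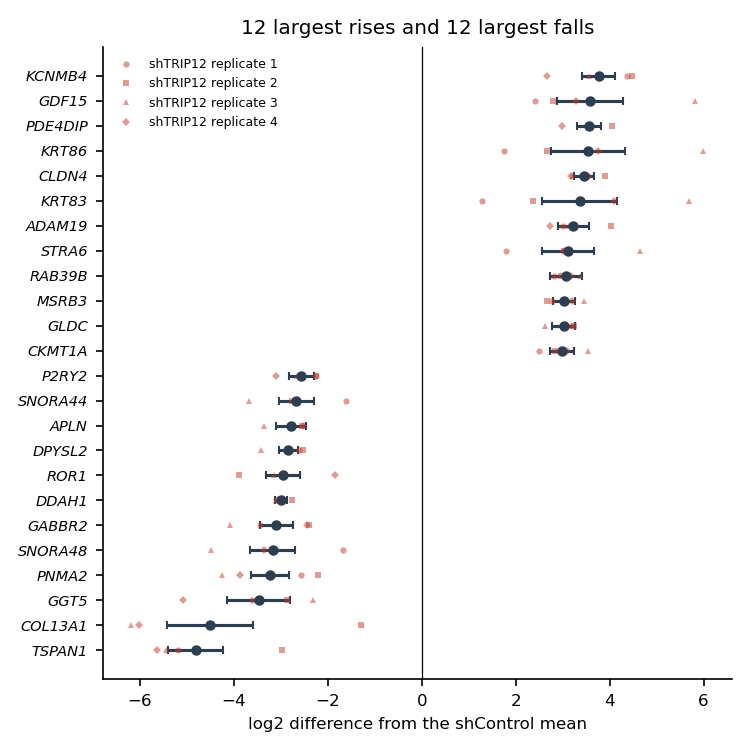
Log2 fold change of the 12 genes with the largest rises and the 12 with the largest falls (dark points, with bars for the SE of the fit), and the log2 difference of each shTRIP12 array from the shControl mean (red points). KCNMB4, at 3.76, and TSPAN1, at −4.81, lie farthest from 0.

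Probe and sequence features bear on several named genes. The annotated 3′ UTRs of DDAH1, IDI1, BUB3, CHORDC1, RNF168, CD44 and KMT2A hold the sequence GGAAACAT, which TRIP12 transcripts also hold. Those of COL13A1, ECT2, GINS4, BAG3, RIF1, SLC2A1, SOD2, TEAD1, NEDD4L, LTBP2 and TXNRD1 hold its 7-base parts GAAACAT or GGAAACA. All of these genes fell on the probes used. The 3′ UTRs of STRA6, MSRB3, CCND2, FBXW7, GABARAPL1 and ATF5, which rose, hold GAAACAT or GGAAACA too. Chromosome 11 carried 5.55% of the genes tested and 20.04% of those that fell. Of the 98 named genes other than TRIP12, 68 kept their call whichever single array was left out and 30 did not.

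Of 37 gene lists, 10 passed the camera test at its preset correlation, each of them lower in shTRIP12. With an estimated correlation 0 passed, and 3 lists had an unadjusted p under 0.05. The estimated correlation was 0.82 for DNA replication, 0.75 for mitosis, 0.69 for ribosome biogenesis and 0.62 for the proteasome, against the preset 0.01. It was 0.36 to 0.38 for heat shock, repair and NF-kB, 0.23 for cholesterol, 0.03 for YAP/TAZ and 0.008 for hypoxia. Where the estimate lies far above the preset, the camera p at the preset overstates the evidence. With slide as a block 10 lists passed, on slide 1 alone 13 and on slide 2 alone 6. Under quantile normalization 3 passed, the cholesterol, mitosis and proteasome lists, and with normexp background as well 4, these and ribosome biogenesis. By fry, which asks whether the members of a list move one way without comparing them with other genes, 5 lists passed. They were 3 of the 10, cholesterol, hypoxia and YAP/TAZ (adjusted p = 0.00456, 0.00456 and 0.0179), and 2 others, apoptosis regulators and epithelial markers (adjusted p = 0.0179 each). The other 7 of the 10 did not pass by fry, with adjusted p = 0.205 for mitosis, 0.0693 for the proteasome, 0.441 for DNA replication, 0.152 for heat shock and 0.291 for repair, ribosome biogenesis and NF-kB. With each gene centred on its mean over the 8 arrays, the list median of every shTRIP12 array lay apart from every shControl array in 6 lists (two-sided exact permutation p = 0.0286 each). These were the cholesterol, mitosis, proteasome, hypoxia, YAP/TAZ and apoptosis lists, and 1.06 lists would do so by chance. With each gene centred on its shControl mean, as in the array medians given below, the heat shock, integrin and p53 target lists separated too, but that centring treats the groups unequally and was not tested. The number of negative list medians depends on the scale. It was 23 on the main scale, 35 on the array-median scale and 19 when scaled to the 75th percentile of probes above background on all arrays.

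**Figure D3:**
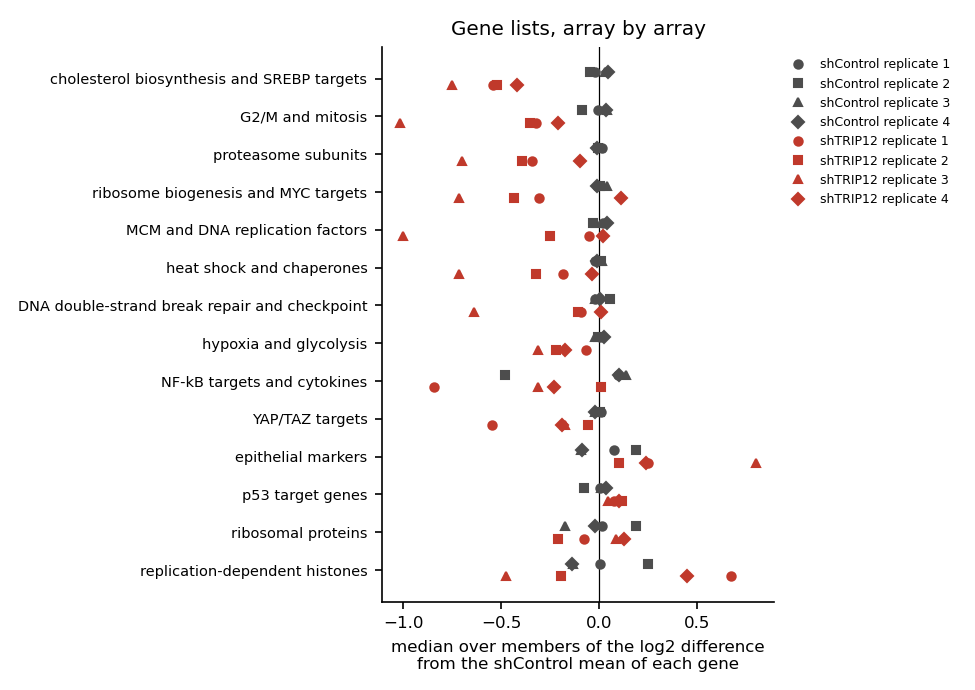
Median over the members of a list of the log2 difference from the shControl mean, 1 point per array, for the 10 lists that passed camera at its preset correlation and 4 others (epithelial markers, p53 targets, ribosomal proteins, histones). The shTRIP12 arrays of the cholesterol list lie between −0.75 and −0.42, and replicate 3 lies lowest in the mitosis and DNA replication lists.

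More than 10 genes of cholesterol synthesis and SREBP targets fell. Of 26 measured genes of cholesterol biosynthesis and SREBP targets, 15 fell, 0 rose and 11 did not pass over all genes, with 18 lower adjusted over the list alone. DHCR7, which encodes a late reductase of cholesterol synthesis, fell 2.80-fold (log2 −1.49, SE 0.16, limma adjusted p = 0.00113). IDI1 and MVD, enzymes of the mevalonate pathway, fell 2.09-fold and 1.76-fold (limma adjusted p = 0.00402 and 0.00915). The fatty acid synthase gene FASN, an SREBP target, fell 1.75-fold (log2 −0.80, SE 0.17), a call that ended without shControl replicate 1 or 4 (limma adjusted p = 0.051 and 0.0539). The list median was −0.58 (camera adjusted p = 2.7e-10), and the medians of the shTRIP12 arrays were −0.54, −0.52, −0.75 and −0.42. The list had an adjusted p = 0.488 with an estimated correlation. Of the 15 genes that fell, 1, DHCR7, lies on chromosome 11.

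Some genes of cell division and of DNA repair fell. In the list of 46 genes of G2/M and mitosis 7 fell, 1 rose and 38 did not pass over all genes, with 16 lower and 1 higher adjusted over the list alone (median −0.48, camera adjusted p = 9.4e-09, and adjusted p = 0.864 with an estimated correlation). The cytokinesis regulator ECT2 fell 2.83-fold (log2 −1.50, SE 0.27, limma adjusted p = 0.00798), and MKI67, the Ki-67 proliferation antigen, fell 2.10-fold. The spindle checkpoint gene BUB3 fell 1.97-fold, whereas CDC25B, a phosphatase that activates mitotic kinases, rose 1.66-fold (limma adjusted p = 0.00882 and 0.008). Of 37 MCM and DNA replication factors 2 fell, the polymerase subunit gene POLE2 (log2 −0.76, SE 0.20) and the helicase factor gene GINS4 (−0.71, SE 0.17), and 0 passed adjusted over the list alone. That list had a median of −0.35 (camera adjusted p = 0.00222, and adjusted p = 0.864 with an estimated correlation). Without shTRIP12 replicate 3 its median was −0.16 and its call ended (adjusted p = 0.133), and on slide 2 alone its median was 0.003 (adjusted p = 0.950, with 8.1e-07 to 0.950 over its alternatives). Of 36 genes of double-strand break repair and checkpoint 7 fell, 4 of them on chromosome 11, and 7 adjusted over the list alone. They include the histone gene H2AX (log2 −0.96, SE 0.26), the damage-signalling ligase gene RNF168 (−0.84, SE 0.20), the repair-choice gene RIF1 (−0.79, SE 0.21) and the checkpoint kinase gene CHEK1 (−0.73, SE 0.15), of which H2AX and CHEK1 lie on chromosome 11. The list median was −0.17 (camera adjusted p = 0.0177, and adjusted p = 0.864 with an estimated correlation). That call ended without shTRIP12 replicate 3 (median −0.02, adjusted p = 0.144), without shControl replicate 3 (adjusted p = 0.0517), on slide 2 alone (median 0.01, adjusted p = 0.317), without shTRIP12 replicate 3 and shControl replicate 2 together (adjusted p = 0.102) and without the genes of chromosome 11 (adjusted p = 0.0913), with 0.00258 to 0.864 over all its alternatives. The mitosis list had a median of −0.28 without shTRIP12 replicate 3. The median of the shTRIP12 arrays was lowest in replicate 3 for mitosis (−1.02, the others −0.35 to −0.21) and also lowest in replicate 3 for replication (the others −0.25 to 0.02). Leaving out single arrays of either group ended the calls of MKI67, POLE2, H2AX, RNF168 and RIF1, with adjusted p of at most 0.0749, 0.096, 0.0958, 0.0689 and 0.0967. The GINS4 call ended without shControl replicate 1, 3 or 4 (adjusted p = 0.071, 0.0632 and 0.0735). Of 30 G1/S regulators and E2F targets 3 rose and 3 fell (3 and 5 adjusted over the list alone, median −0.27, camera adjusted p = 0.107). That list passed without shControl replicate 2 (adjusted p = 0.0449) and on slide 1 alone (0.00856), with 0.00856 to 0.864 over its alternatives. CCND2, a D-type cyclin gene, was at least 6.999-fold higher and its partner kinase gene CDK6 rose 2.81-fold. Another D-type cyclin gene, CCND1 on chromosome 11, fell 2.13-fold (log2 −1.09, SE 0.20, limma adjusted p = 0.00994), and was picked after its values were seen. None of 25 replication-dependent histone genes passed, over all genes or adjusted over the list alone (median 0.14, camera adjusted p = 0.647), and the list's median was −0.18 on slide 1 alone (adjusted p = 0.0322) and 0.41 on slide 2 alone (adjusted p = 1.9e-05). Without shTRIP12 replicate 3 it was 0.35 (adjusted p = 0.0216).

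Some genes for protein degradation, folding and ribosome assembly fell too. All 32 proteasome subunit genes had negative fold changes on the main scale, 7 fell and 25 did not pass over all genes, with 16 lower adjusted over the list alone. The ATPase subunit genes PSMC3 and PSMC6 fell 1.95-fold and 1.68-fold, the regulatory subunit gene PSMD2 1.80-fold and the core subunit gene PSMA1 1.79-fold (limma adjusted p = 0.0121, 0.0143, 0.0235 and 0.0034). PSMC3 and PSMA1 lie on chromosome 11. The list median was −0.38 (camera adjusted p = 1.7e-08, and adjusted p = 0.864 with an estimated correlation). Its array medians were −0.34, −0.39, −0.70 and −0.10 in shTRIP12 replicates 1 to 4, and without replicate 3 the list median was −0.29. Of 20 heat shock and chaperone genes 3 fell (4 adjusted over the list alone, median −0.38, camera adjusted p = 0.00327, and adjusted p = 0.864 with an estimated correlation). The call ended on slide 2 alone (median −0.13, adjusted p = 0.273, with 0.000105 to 0.864 over its alternatives). In shTRIP12 replicates 1 to 4 the medians of this list were −0.19, −0.33, −0.71 and −0.04, and without replicate 3 its median was −0.26. The 3 genes were CHORDC1 (2.38-fold, SE 0.22 log2), an HSP90 co-chaperone gene on chromosome 11, BAG3 (−0.79, SE 0.17), a co-chaperone of HSP70, and STIP1 (−0.66, SE 0.19), whose probe matches only the pseudogene STIP1P3 among annotated transcripts. Of 32 genes of ribosome biogenesis and MYC targets 1 fell, NOLC1, a nucleolar phosphoprotein gene (log2 −0.59, SE 0.17), and 0 adjusted over the list alone (median −0.29, camera adjusted p = 0.000691, and adjusted p = 0.864 with an estimated correlation). The median of that list was −0.17 without shTRIP12 replicate 3, −0.502 without shTRIP12 replicate 4, whose own median was 0.11, and −0.05 on slide 2 alone, where the call ended (adjusted p = 0.439, with 3.9e-08 to 0.864 over its alternatives). Leaving out single arrays ended the calls of PSMD2, PSMC6, BAG3, STIP1 and NOLC1, with adjusted p of at most 0.0701, 0.0518, 0.0548, 0.123 and 0.112. Of 38 ribosomal protein genes 1 fell, RPS13 on chromosome 11 (log2 −0.62, SE 0.13, limma adjusted p = 0.0523 and 0.0557 without shControl replicate 1 or 4), and 1 adjusted over the list alone (median −0.01, camera adjusted p = 0.567).

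Some genes of sugar metabolism fell as well. Of 30 genes of hypoxia and glycolysis 6 fell, 1 rose and 23 did not pass over all genes, with 8 lower and 2 higher adjusted over the list alone. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell 3.44-fold (log2 −1.78, SE 0.21, limma adjusted p = 0.00162). The hexokinase gene HK2 fell 2.36-fold, on a probe without an exact match among annotated transcripts, LDHA, a lactate dehydrogenase gene on chromosome 11, 2.24-fold and the glucose transporter gene SLC2A1 2.12-fold. The list median was −0.26 (camera adjusted p = 0.0199, and adjusted p = 0.488 with an estimated correlation). The call ended without shControl replicate 3 (adjusted p = 0.0557), without shTRIP12 replicate 4 (adjusted p = 0.0692) and on slide 2 alone (median −0.14, adjusted p = 0.135), with 0.00383 to 0.488 over its alternatives. Of 31 nuclear-encoded genes of oxidative phosphorylation 4 fell and 1 rose, as they did adjusted over the list alone (median −0.12, camera adjusted p = 0.0556). The list passed without shTRIP12 replicate 4 (adjusted p = 0.0172), on slide 1 alone (0.0406), on the array-median scale (0.0256) and with no filter on dim probes (0.0293), with 0.0172 to 0.969 over its alternatives. SDHD, a subunit gene of succinate dehydrogenase on chromosome 11 whose probe has no exact match, fell (log2 −0.78, SE 0.14) and the cytochrome oxidase subunit gene COX7C rose 2.38-fold (SE 0.19). Of 22 NRF2 targets 1 fell, the thioredoxin reductase gene TXNRD1 (log2 −1.21, SE 0.30), and 0 passed adjusted over the list alone (median −0.03, camera adjusted p = 0.609). The TXNRD1 call ended without single arrays of either group (adjusted p of at most 0.0712).

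Inflammatory genes moved in both directions. Of 18 NF-kB targets and cytokines 4 fell, over all genes and adjusted over the list alone, with a median of −0.36 (camera adjusted p = 0.0277, and adjusted p = 0.864 with an estimated correlation). BIRC3, an inhibitor of apoptosis on chromosome 11, fell 3.42-fold (log2 −1.77, SE 0.33, limma adjusted p = 0.00963). The chemokine genes CXCL2 and CXCL1 fell 2.43-fold and 2.23-fold and SOD2, a mitochondrial superoxide dismutase gene, 1.73-fold. The list's call ended without shControl replicate 3 (adjusted p = 0.154), shTRIP12 replicate 1 (median −0.10, 0.268) or shTRIP12 replicate 4 (0.0539), on slide 1 alone (0.147), on the array-median scale (0.149) and with no filter on dim probes (0.0599), with adjusted p of 0.000923 to 0.864 over its alternatives. Its array medians were −0.84, 0.006, −0.31 and −0.23 in shTRIP12 replicates 1 to 4. The calls of CXCL2 and CXCL1 ended without single arrays of either group (adjusted p of at most 0.103 and 0.12). Of 26 genes of the type I interferon response 5 fell and 2 rose (12 and 5 adjusted over the list alone, median −0.41, camera adjusted p = 0.161). The list passed without shControl replicate 2 (adjusted p = 0.000281), on slide 1 alone (0.0329), with no filter on dim probes (0.0194) and without the genes of chromosome 11 (0.0253), with 0.000141 to 0.864 over its alternatives. Besides IFI44, the antiviral gene RSAD2 was at least 9.51-fold lower, with a fitted log2 fold change, which is no bound, of −5.10 without shControl replicate 2 and −3.60 without shControl replicate 3. Among the control arrays themselves the median of this list ran from −0.54 in shControl replicate 2 to 0.56 in shControl replicate 3. Of 18 genes of MHC class I antigen presentation 4 rose and 0 fell (7 and 2 adjusted over the list alone, median 0.01, camera adjusted p = 0.609). They include the immunoproteasome gene PSMB9 (log2 1.44, SE 0.42) and HLA-B (0.79, SE 0.23), whose groups overlapped and whose calls ended without single arrays of either group (adjusted p of at most 0.103 and 0.11).

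Genes of adhesion, cell shape and the matrix diverged. Of 14 YAP/TAZ targets 3 fell, over all genes and adjusted over the list alone. They were CCN1, a secreted matricellular protein gene (log2 −1.11, SE 0.14), and on chromosome 11 TEAD1, the DNA-binding partner of YAP (−1.07, SE 0.16), and FJX1 (−0.95, SE 0.26), whose call ended without single arrays of either group (adjusted p of at most 0.102). The list median was −0.39 (camera adjusted p = 0.0277, and adjusted p = 0.535 with an estimated correlation). The call ended without shControl replicate 3 (adjusted p = 0.068), without shTRIP12 replicate 1 (0.183), on slide 1 alone (0.183), on the array-median scale (0.0922), with the probe GC correction (0.0514) and without the genes of chromosome 11 (0.157), with 0.00698 to 0.535 over its alternatives. Of 18 epithelial markers 3 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.43, camera adjusted p = 0.107). The list passed on the array-median scale (median 0.26, adjusted p = 0.0485) and by fry, with 0.0179 to 0.670 over its alternatives. CLDN4 headed the rises, while OCLN, another tight-junction gene, fell (log2 −0.76, SE 0.19), a call that ended without single arrays of either group (adjusted p of at most 0.0878). Of 30 integrin and cell-matrix adhesion genes 3 rose and 4 fell (3 and 6 adjusted over the list alone, median −0.21, camera adjusted p = 0.107, and 0.0284 without shTRIP12 replicate 2). The integrin gene ITGB8 was at least 6.79-fold higher, on a probe without an exact match. CD44, the hyaluronan receptor gene on chromosome 11, fell 2.75-fold on the probe used, but its other probe stood at 1.99 and the mean of the probes at 0.27. Of 19 mesenchymal and EMT markers 1 rose, COL5A1 (log2 1.90, SE 0.22), and 1 fell, COL6A3 (−1.18, SE 0.28), both fibrillar or microfibrillar collagen genes, with the same counts adjusted over the list alone (median 0.06, camera adjusted p = 0.718). Of 16 matrix proteases and inhibitors 2 rose and 1 fell (2 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.848), among them ADAM19 and the urokinase gene PLAU (log2 −1.26, SE 0.36). The calls of COL6A3 and PLAU ended without single arrays of either group (adjusted p of at most 0.0664 and 0.113).

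Single stress and signalling genes changed in both directions. Of 24 p53 target genes 5 rose and 1 fell (6 and 2 adjusted over the list alone). The list had a median of −0.01, a mean of 0.21 and an upward camera test (adjusted p = 0.718). GDF15 and BBC3, a pro-apoptotic BCL-2 family gene (log2 1.68, SE 0.36), led the rises. Of 32 genes of the unfolded protein and integrated stress response 4 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.06, camera adjusted p = 0.848). The transcription factor genes DDIT3 (log2 1.90, SE 0.36) and ATF5 (1.64, SE 0.38, probe without an exact match) rose. Of 32 apoptosis regulators 7 fell and 1 rose (8 and 2 adjusted over the list alone, median −0.11, camera adjusted p = 0.0947, fry adjusted p = 0.0179), including HRK, a pro-apoptotic BH3-only gene (log2 −1.83, SE 0.35), and BIRC3. By camera that list passed without shControl replicate 2 (adjusted p = 0.0153), on slide 1 alone (0.0329) and with no filter on dim probes (0.0373), with 0.0153 to 0.535 over its alternatives. Of 31 autophagy and lysosome genes 5 rose and 2 fell, as they did adjusted over the list alone (median 0.05, camera adjusted p = 0.676). WIPI1 (log2 0.87, SE 0.17) and GABARAPL1 (0.86, SE 0.24, probe without an exact match), both of autophagosome formation, were among them. Of 28 MAPK output genes 3 rose and 6 fell (3 and 7 adjusted over the list alone), with a median of 0.06, a mean of −0.07 and a downward camera test (adjusted p = 0.609). The EGF receptor ligand gene HBEGF fell (log2 −2.19, SE 0.49) and another, AREG, rose (1.64, SE 0.48). Of 24 immediate early genes 3 rose and 4 fell, as adjusted over the list alone (median −0.17, camera adjusted p = 0.263). The nuclear receptor gene NR4A3 was at least 5.93-fold higher and the antiproliferative gene BTG2 rose (log2 1.28, SE 0.23). Of 14 Wnt/beta-catenin targets 2 rose and 4 fell (2 and 5 adjusted over the list alone), with a median of −0.02, a mean of 0.03 and a downward camera test (adjusted p = 0.473). The Wnt inhibitor gene APCDD1 rose (log2 3.65, SE 0.24), by an amount that is not exact because 1 of its shControl arrays was at background, and the transcription factor gene TCF7 fell (−2.48, SE 0.27). Of 17 TGF-beta targets 1 rose, ID2, an inhibitor of differentiation (log2 2.30, SE 0.59), and 2 fell, among them LTBP2, a TGF-beta binding protein gene (−0.96, SE 0.19), as adjusted over the list alone, with a median of −0.07, a mean of 0.08 and a downward camera test (adjusted p = 0.609). Leaving out single arrays ended the calls of ATF5, GABARAPL1, HBEGF, AREG and ID2 (adjusted p of at most 0.0546, 0.117, 0.0576, 0.123 and 0.0797).

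Single ubiquitin ligase, chromatin regulator and cell-type marker genes changed as well. Of 23 HECT-type ligases 3 fell and 1 rose (4 and 1 adjusted over the list alone, median −0.08, camera adjusted p = 0.438), with NEDD4L, a ligase for membrane channels, falling 2.53-fold beside TRIP12. Of 11 reported TRIP12 substrates and partners 3 fell and 1 rose, as adjusted over the list alone, with a median of 0.03, a mean of −0.06 and a downward camera test (adjusted p = 0.619). FBXW7, a substrate receptor of an SCF ubiquitin ligase, rose (log2 0.93, SE 0.13) and RNF168 fell. Of 29 SWI/SNF and chromatin regulator genes 4 fell and 0 rose, as adjusted over the list alone (median −0.12, camera adjusted p = 0.218). They include ACTL6A (log2 −0.79, SE 0.19), whose call ended without single arrays (adjusted p of at most 0.0759), and on chromosome 11 KMT2A (−0.74, SE 0.15), a histone methyltransferase gene whose probe also matches AP001267.5. Of 13 pancreatic ductal and progenitor markers 1 fell, the pioneer factor gene FOXA1 (log2 −1.34, SE 0.15), as adjusted over the list alone, with a median of 0.04, a mean of −0.04 and a downward camera test (adjusted p = 0.609). Of 15 endocrine and neuroendocrine markers 1 fell, PAX6 on chromosome 11 (log2 −0.94, SE 0.13, its 3 probes between −0.94 and −0.02), as adjusted over the list alone (median 0.22, camera adjusted p = 0.609). None passed among 10 acinar, 9 fibroblast and stellate, and 9 haematopoietic and endothelial markers, over all genes or adjusted over the list alone (medians 0.09, 0.05 and 0.10, camera adjusted p = 0.759, 0.81 and 0.759).

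The changes were not spread evenly over the chromosomes. On chromosome 11, 283 of 1130 genes fell and 43 rose, with a median log2 fold change of −0.18 (camera adjusted p = 3.9e-08, and adjusted p = 0.734 with an estimated correlation). Medians of the chromosome 11 genes in the shTRIP12 arrays were −0.14, −0.29, −0.21 and −0.19, below every shControl array (−0.08 to 0.06, two-sided exact permutation p = 0.0286). It was the only 1 of the 23 chromosomes without overlap, against 0.657 by chance. Over the first 10 Mb the median was 0.07, with 12 of 192 genes higher and 6 lower. Between 20 and 30 Mb it was −0.55, and between 60 and 70 Mb −0.35, where 87 of 281 genes fell and 4 rose. Chromosome 19 moved the other way, with 173 of 1372 genes higher and 18 lower (median 0.14, camera adjusted p = 0.0014, and 0.979 with an estimated correlation, exact permutation p = 0.0571). Smaller shifts were found for chromosome 4 (84 of 667 genes higher and 17 lower, median 0.11, camera adjusted p = 0.0287) and chromosome 1 (100 of 2039 genes higher and 193 lower, median −0.06, camera adjusted p = 0.0455). With an estimated correlation 0 of the 23 chromosomes passed, with adjusted p = 0.979 for chromosomes 4 and 1 and an unadjusted p = 0.0319 for chromosome 11. With slide as a block 3 chromosomes passed, on slide 1 alone 2 and on slide 2 alone 5, and the chromosome 11 median was −0.18 and −0.21 on slides 1 and 2. Chromosome 4 was no longer past the threshold without shControl replicate 2 (adjusted p = 0.0566), shTRIP12 replicate 1 (0.211) or shTRIP12 replicate 4 (0.202), with 7.9e-07 to 0.979 over its alternatives. Chromosome 1 lost its call in 6 of the 8 cases, all but those without shTRIP12 replicates 2 and 3, with adjusted p from 0.0507 to 0.196 there and 0.0131 to 0.979 over its alternatives.

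**Figure D4:**
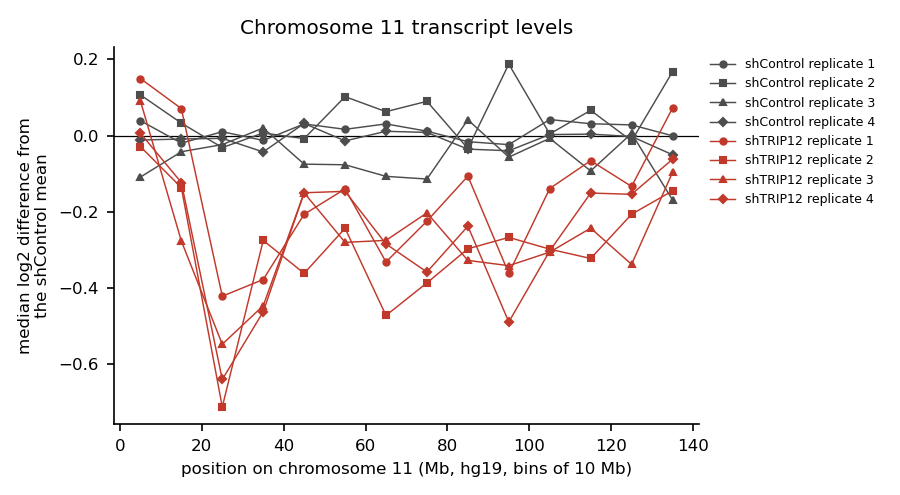
Median log2 difference from the shControl mean of the genes in each 10-Mb window of chromosome 11 (hg19), 1 line per array. Between 60 and 70 Mb the shTRIP12 arrays lie between −0.47 and −0.28 and the shControl arrays between −0.11 and 0.06.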

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

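Among the tests in this part, the comparison of the slides for chromosome 11 and the bound of −0.10 for the lists without shTRIP12 replicate 3 were chosen only after the result was seen, while leaving out each array in turn was planned. The values below stood apart because 1 array lay far from the other 3 of its group, by a gap of more than Dixon's 95% critical share of the group's range. Chance alone gives about 1 in 20 such cases, or 14 among the 280 groups of 4 arrays examined, and 26 were found, 9 of them in shControl replicate 2, 8 in shControl replicate 3, 5 in shTRIP12 replicate 3, 3 in shTRIP12 replicate 2 and 1 in shTRIP12 replicate 4. Gene values are log2 units relative to the array's 75th percentile, and list values are medians of the log2 difference from the shControl mean.

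In shControl replicate 2, GDF15 stood at 2.47 with the other controls at 0.84 to 0.97, and KRT83 at −2.21 with the others at −3.19 to −3.06. TSPAN1 was 3.54 there against 4.93 to 5.16, COL13A1 2.13 against 2.61 to 2.64 and APLN −2.20 against a highest of −0.76 and a lowest of −0.997. PSMC3 was 4.51 against 4.83 to 4.89 and TCF7 −0.40 against 0.55 to 0.62. The NF-kB list had a median of −0.48 in that array against 0.09 to 0.14, and the autophagy and lysosome list −0.074 against 0.02 to 0.03. In shControl replicate 3, STRA6 stood at −3.41 against others from −2.13 upward, GGT5 at 0.93 against 3.16 to 3.31 and SGCE at −7.64 against −7.15 to −7.07. PSMD2 was 7.31 against 7.47 to 7.49, CCND2 −5.73 against −7.17 to −7.05 and ITGB8 −8.01 against −7.48 to −7.45. NEDD4L was 3.35 against 3.62 to 3.67 and FOXA1 −3.87 against −3.42 to −3.32. SGCE, CCND2 and ITGB8 were at background on all shControl arrays, so those values differ only within background.

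In shTRIP12 replicate 2, TSPAN1 stood at 1.69 with the other shTRIP12 arrays at −0.96 to −0.52. TRIM59 was −7.90 there against −6.48 to −6.45 and PLSCR1 −7.91 against −7.47 to −7.40, both at background on all shTRIP12 arrays. In shTRIP12 replicate 3, PSMD2 was 5.95 against 6.78 to 6.84, GINS4 4.01 against 4.64 to 4.74 and HK2 1.24 against 2.15 to 2.33. ITGB8 was −1.73 against −3.19 to −3.01 and RSAD2, at background on all shTRIP12 arrays, −5.29 against −7.35 to −7.05. In shTRIP12 replicate 4, CDK6 was 4.22 against 3.44 to 3.51.

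Each count was compared with those of the other splits of the 8 arrays. For changed genes, only 1 of the 35 splits into 4 and 4, the real split, gave 2986. The highest count of any other split was 0. A share of 1 in 35 (0.0286) is the smallest this test can give. Every other split puts arrays of both groups on each side, so a group difference of any cause widens its spread and lowers its count. The count of 0 thus does not measure what chance alone would give, and chance is not excluded by it. For gene lists, 23 of the 35 splits gave at least the real 10, the highest of the others 22, so chance is not excluded, and members of a list vary together between arrays of 1 group. For chromosomes, 16 of the 35 splits gave at least the real 4, the highest of the others 5, so chance is not excluded for their number either.

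The lower mitosis and replication lists, for which the splits leave chance open, were weighed because shTRIP12 replicate 3 lay lowest in both. Without that array the median of the mitosis list was −0.28. Each of the other shTRIP12 arrays (−0.35 to −0.21) lay below every shControl array (−0.09 to 0.04). This argues against 1 array as the whole of that fall. The bootstrap SE of 0.03 was taken over member genes, which vary together, so it does not measure the spread between arrays. For the DNA replication list the median was −0.16 (SE 0.09, also over genes), too close to the bound of −0.10 to tell whether that array alone decides it. Degraded RNA in replicate 3 is argued against by a median difference between the 5′ and 3′ probes of a gene of −0.0196 log2 units in that array. A slower proliferation of the shTRIP12 cells, or of the culture behind replicate 3, may account for the pattern and was not tested.

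The fall of chromosome 11 genes, by a median of −0.21 log2 units relative to all other genes, was weighed next. Probe GC content is argued against, since its median was 45% on chromosome 11 and 45% elsewhere. The difference was −0.215 after a loess correction (SE 0.02 over genes, which are not independent), a correction that could move it little. A plain slide difference cancels, because each slide held arrays of both groups. The difference was −0.232 on slide 2 and −0.235 on slide 1 alone, so the fall was not confined to 1 slide. A lower copy number in the shTRIP12 cells beyond 20 Mb could give such a pattern, as a hypothesis, and would lower dim and bright genes alike, by amounts within 0.15 of each other. The differences were −0.11 for the dimmest genes, −0.34 for the middle and −0.47 for the brightest, each relative to genes of like brightness elsewhere. They span 0.36, which counts against an even lowering of all genes, although even the dimmest lay below the bound of −0.10. Whether background compresses changes of dim probes was not tested, so copy number and a regional change of transcription cannot be told apart from these arrays.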

How the results depend on the processing

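Leaving out shTRIP12 replicate 3 and shControl replicate 2 together, the probe GC correction and leaving out chromosome 11 were chosen only after the results were seen. TRIP12 kept its direction and its side of the threshold in 22 alternatives (log2 −3.25 to −1.28, adjusted p 0.000191 to 0.0488; without single arrays −3.10 to −2.66), and its other probe alone gave 0.38. The count of changed genes was 2986 and stayed within 1.5-fold under the other normalizations, probe choices and array weights. It was 1270 with no filter on dim probes, 445 and 142 within slide 1 and slide 2 alone, where fewer arrays were tested, and 1665 with replicate number as a block. Without single arrays it was 1323 to 3831, and lower by over 1.5-fold without shControl replicate 1 (1389), 3 (1770) or 4 (1323). For the filter, the replicate block and the single arrays the cause was not tested. Changes of at least 2-fold (1022) numbered 429 with normexp background and quantile normalization, 445 and 142 within slide 1 and slide 2, and 757 to 1244 without single arrays. With quantile normalization alone they numbered 882. The normexp setting added 50 to the intensities, while the median processed signal of an array was 25.7 to 36.97, so it shrinks the folds of dim genes. How much of the drop to 429 this explains was not tested. Gene lists (10) numbered 4 with normexp and quantile, 3 with quantile normalization, 6 within slide 2, 0 with an estimated correlation and 5 with fry. Without single arrays they numbered 6 to 13, with 6 without shControl replicate 3. For most of the 10 lists the estimated correlation lay above the preset, though not for hypoxia. For the other settings the cause was not tested. Chromosomes (4) numbered 2 with normexp and quantile, 2 with quantile normalization, 2 within slide 1, 0 with an estimated correlation, and 2 to 5 without single arrays, with 2 without shControl replicate 2, shTRIP12 replicate 1 or shTRIP12 replicate 4, and the cause was not tested. The sign turned for CD44 with the mean of its probes (0.27), which averages −1.46 and 1.99. For the replication-dependent histones it turned within slide 1 (−0.18), and within slide 2 the medians of the MCM and DNA replication list (0.003) and of the double-strand break repair list (0.01) turned positive without passing the threshold, and the cause was not tested. The 3 added alternatives gave, in the order above, 2007 and 3112 genes for the first and second, 13, 9 and 9 lists, and 4 and 3 chromosomes for the first and second. Of the 98 named genes that passed, 96 kept their call with slide as a block, 84 with replicate number as a block, 34 within slide 1 and 22 within slide 2. The cholesterol list kept its call in 23 of 24 alternatives, and the mitosis and proteasome lists in 22. Chromosomes 11 and 19 each kept theirs in 16 of 17, 4 in 10 and 1 in 4. Replicate numbers do not pair the arrays: residuals of arrays with the same number correlated by −0.16 to 0.08, with different numbers by −0.19 to 0.22. Signal over background limits folds of genes at background in 1 group to lower bounds on the main scale, and some alternatives gave smaller fitted folds.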

Other observations

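The sets and sites in this part, and every test of them, were chosen only after values had been seen. Small nucleolar RNAs were split by class. Of 102 measured H/ACA RNAs, which guide pseudouridylation and are named SNORA, 35 fell and 5 rose, while of 130 C/D RNAs, which guide ribose methylation and are named SNORD, 6 fell and 4 rose (limma). A fall was thus found for 34.3% of the first class and 4.62% of the second (Fisher's exact p = 4.4e-09, over RNAs that are not independent). Without shTRIP12 replicate 3 the counts of falls were 31 and 6, and without shControl replicate 2 they were 31 and 4. The medians were −0.25 for SNORA and 0.03 for SNORD. The SNORA set had a camera p of 2.0e-08 at the preset correlation and 0.274 with an estimated correlation, and its array medians ran from −0.29 to 0.36 in shControl and from −0.38 to −0.14 in shTRIP12 (exact permutation p = 0.0571). Most of these RNAs are processed from introns of host genes. The probes of SNORA48 and SNORA44 also match transcripts of their hosts EIF4A1 and SNHG12, and the other probes of these classes were not searched. Whether a probe read the mature RNA or a host or precursor transcript was not tested, so the falls are those of probe signals. Of 118 measured host genes 12 fell and 0 rose (median −0.02, camera p = 0.0128 at the preset correlation and 0.436 with an estimated one). SNORA51 had a log2 fold change of −2.53 and its host NOP56 −0.41, SNORA62 −2.39 and its host RPSA 0.06, and SNORA5C −1.93 and its host TBRG4 −0.15. Of 95 SNORA with a measured host 58 lay below it (median difference −0.19), and of 105 SNORD 37 (0.18).

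Genes that changed at least 2-fold in 1 direction lay next to each other more often than in permutations of their order. Among 14674 symbol-named genes in chromosomal order 72 neighbouring pairs did so, against a median of 22 and a maximum of 39 in 1000 permutations of the order (p = 0.001, the smallest they can give). Without chromosome 11 there were 60 pairs, against a median of 19 and a maximum of 32. Runs of 3 or more included EREG, AREG and PARM1 on chromosome 4, where EREG and AREG encode EGF receptor ligands, and CYFIP2, NIPAL4 and ADAM19 on chromosome 5, all higher. On chromosome 19 DBP, CA11 and NTN5 were higher. CMIP, PLCG2 and MPHOSPH6 on chromosome 16 were lower, as were SNORA5A, SNORA5B and SNORA5C on chromosome 7 and SNORA32, SNORD6, SNORA1 and SNORA8 on chromosome 11. The run on chromosome 7 lies within 1 host gene, TBRG4, and that on chromosome 11 within TAF1D. The permutations treated such RNAs, and related neighbours such as EREG and AREG, as separate genes. Pairs of this kind can arise without a regional effect, and the count without them was not tested.

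Genes whose 3′ UTR held certain 7-base sequences were lower in shTRIP12. Over 12944 genes with an annotated 3′ UTR and 15965 sequences, those with GAAACAT (2007 genes) differed by −0.10 log2 units (t = −6.79) and those with GGAAACA (2207 genes) by −0.09 (t = −6.71), beyond the lowest t of −5.14 in 100 permutations. Genes with the joined GGAAACAT numbered 630 and differed by −0.07 (t = −3.05), no more than with either part. These differences are adjusted for the length and GC content of the 3′ UTR. Without that adjustment 16.2% of the genes with GGAAACAT fell against 8.40% of genes without it, and 9.05% rose against 8.14%. TRIP12 transcripts hold AGGAAACAT in 4 of 17 cases. In a scan of slide 1 alone GAAACAT had the lowest t of all the sequences, and its t on slide 2 was −6.60. In a scan of slide 2 alone the same sequence was lowest, and its t on slide 1 was −5.96, so the pattern was not confined to 1 slide. A plain slide difference cancels, because each slide held arrays of both groups. A candidate explanation is that the expressed hairpin acts on transcripts matching its seed, in which case some falls are not due to TRIP12. Such a match would leave the reverse complement at a t above −2, and that of GAAACAT had a t of −1.10 on slide 2 and 0.10 on slide 1. The reverse complement would lie there without a hairpin too, so these values do not favour one. The hairpin sequence was not given in the sources used here, so a hairpin seed cannot be told apart from another factor that binds the same sequence. No annotated 3′ UTR was there to search for 7428 tested genes.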
